A study of Gallus gallus with 2 samples.

How the data were processed

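Coronal sections of 10 µm were cut from snap-frozen telencephalons of broiler chickens aged 15 days and placed on Nova-ST chips, per the labels' protocols. The tissue was permeabilised with pepsin, captured RNA was reverse transcribed, and the amplified cDNA was sequenced. The labels name 2 sections, plate 5 and plate 12, and put both in a single group, so every comparison of groups is between regions of the same sections. The labels do not say whether the sections came from separate animals. P-values therefore cover no more than the spread between these 2 sections, which may be technical and was partly or wholly pooled over genes.

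The deposited files list, per the file headers, a whole-number count of molecules for each gene at each spot position, with no normalization. The submitters' processing notes name bcl2fastq and STARsolo and the genome builds galGal6 and mm10, without versions or roles, and the role of the mouse build is not given in the sources used here. How UMIs were collapsed and which filters were applied is not given in the sources used here either. The physical size of a coordinate unit is likewise not given. The exonic count repeated the total count in every entry and was not used. Of 15438 gene names, 5947 were symbols, 5913 of them present in the reference table of gene names. None of the 9491 Ensembl identifiers matched that table, so these genes stay unnamed; they held 48.0% of the UMIs on plate 5 and 42.6% on plate 12. No mitochondrial gene carried a symbol, so a mitochondrial share could not be computed. The reference assembly differed from the builds named, and no coordinates are printed.

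The following choices were made before the data were examined. UMIs were summed in square bins of the smallest side, from a fixed series, that gave a median of at least 1000 UMIs per bin over tissue in both sections, which was 800 units, with a median of 2208 UMIs on plate 5 and 2345 on plate 12. Bins over tissue without UMIs were then left out, which gave medians of 2240 and 2364. Bins over tissue were those above the Otsu threshold of the log-scaled total (smoothed with a sigma of 1 bin) in connected areas of at least 1% of such bins. Genes were split at random (seed 1) into a clustering part of 7656 and a testing part of 7782 genes, with every gene of the lists in the testing part, so that no gene that defined a region was tested. Counts were scaled to 10000 UMIs per bin and log-transformed, and the 2000 most variable clustering genes were standardised within each section, reduced to 30 principal components and clustered by the Leiden method (15 neighbours, resolution 0.5, modularity). A region entered a test when it held at least 1% of the bins over tissue in each section. Each region was called by the leading clustering genes with a symbol and at least 20 CPM. No doublet caller or deconvolution was run, since a bin is a small area and not a cell.

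UMIs were summed per region and section and tested with edgeR's quasi-likelihood test after filterByExpr and TMM scaling, with the section as a block, giving 4 sums and 1 residual degree of freedom per comparison, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. With so few sums the estimate of spread leaned on the other genes, entirely so for the COL8A1/HES6 and OSR1/CCN3 regions. In these regions a gene's own disagreement between the sections therefore did not widen its SE or raise its p-value. SEs are the size of the fitted log2 fold change divided by the square root of the test's F statistic, so they restate the test. SDs are over the CPM of the sections, without TMM factors. Log2 differences given for a single plate had 1 CPM added to both levels, which shrinks them where levels are low. The block was checked by the correlation across genes between the section differences of the 2 kinds of sum, which was 0.707 in the comparison of the NHLH2/AVP region and 0.476, 0.560 and 0.478 for the APOH/PLLP, COL8A1/HES6 and OSR1/CCN3 regions; both sums of a pair come from the same section. The design named a striatal against a pallial class, assigned by anchor genes. Of 13 anchor genes 9 were in the files, with 1 striatal and 1 pallial gene among them, so the comparison was run as assigned but is named by regions. A comparison of each pallial region with the other pallial regions could not be run, because 1 region alone was assigned to that class among those that entered. Regions that did not enter were described on plate 12 alone.

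A set of 21 gene lists was fixed in advance, with 126 of 233 genes in the files: glutamatergic, striatal, GABAergic, interneuron, pallidal and cholinergic, oligodendrocyte, oligodendrocyte precursor, astrocyte, ventricular, choroid plexus, vascular, meningeal, microglial, red cell, immediate early, mammalian upper and deep cortical layer, hippocampal, pallial amygdala, avian pallial, and channel and receptor genes. Lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation, where at least 3 members were tested. The anchor genes stayed in their lists, and the lists were also tested without them. In the comparison of the NHLH2/AVP region, genes were named when they were among the 12 highest or 12 lowest by log2 fold change with an adjusted p under 0.05, a log2 difference of at least 1, a mean of at least 20 CPM, the same direction in both sections and a symbol. Of 114 genes at least 2-fold apart, 23 had 20 CPM and 7 of these a symbol; results of some genes are not reported here. In the other regions members of the lists were named, and in regions described on plate 12 alone also the 8 genes with a symbol and at least 20 CPM of the highest log2 ratio (pseudocount 1 CPM); this last rule was set after the data were examined. Shares of bins have exact binomial 95% intervals and ratios of counts 95% Poisson intervals, both for counting error only. The percentile of a list's median was taken among 10000 random lists of genes matched on expression. Members of a random list were drawn independently of each other, so the percentile makes no allowance for list genes that vary together. Moran's I was computed over the 4 nearest bins after thinning to 500 UMIs, which left out 10241 bins of plate 5 and 6750 of plate 12, for genes with at least 1000 thinned UMIs in both sections.

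The test was tried on simulated counts with 200 changed genes. For the comparison of the NHLH2/AVP region, simulated on 6834 genes, 68.7% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, with 14 false among 182 calls. For the APOH/PLLP region (6936 genes) the shares were 11.9%, 43.3% and 84.8%, for the COL8A1/HES6 region (6949 genes) 31.3%, 70.1% and 90.9%, and for the OSR1/CCN3 region (6919 genes) 47.8%, 65.7% and 83.3%. Of the 21 lists, 0 were called in any of these simulations. The simulated genes were drawn independently of each other, so this cannot show how often lists whose members vary together are called falsely. Moran's I of a simulated gene present on 1 side of the section was 0.503.

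Alternatives covered the test (DESeq2), the scaling, the filter on low counts, the section block, 1 fit over all regions, the bin side, the part of the genes used for clustering, the resolution, the standardisation, a stricter mask, leaving out ribosomal protein and haemoglobin genes, and each section alone. The fit over all regions held only those that entered and compared unweighted means of regions, a different contrast from that of summed UMIs. It also estimated the spread from the sums of all these regions, and not from the 4 sums of 1 comparison. It gave the PDE6B/CCN3 region, with 6.59% and 5.57% of the UMIs on plates 5 and 12, the weight of the SPHKAP/RGS6 region, with 52.16% and 40.94%. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, python-igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.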

Results

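Spatial transcriptomes were measured with Nova-ST, an assay that captures polyadenylated RNA from a tissue section on a chip of barcoded spots, in 2 coronal sections of the telencephalon of broiler chickens aged 15 days. The sections are called plate 5 and plate 12 after their labels, which give neither the level of either section along the brain nor the animal it came from. The deposited counts held 157278446 unique molecular identifiers (UMIs) on plate 5 and 170260337 on plate 12. In square bins of 800 coordinate units, 77302 bins of plate 5 and 78848 bins of plate 12 lay over tissue and held UMIs, with a median of 2240 and 2364 UMIs and of 992 and 1107 genes per bin. Ribosomal protein genes held 3.34% of the UMIs on plate 5 and 3.82% on plate 12, and haemoglobin genes 0.0647% and 0.0860%. The 10 most abundant genes took 17.1% of the UMIs on plate 5 and 9.6% on plate 12. The files named 15438 genes, of which 5947 carried a symbol and 9491 only an Ensembl identifier that could not be named here.

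Clustering of the bins gave 8 regions, each called by the leading symbols among the genes used for clustering. The SPHKAP/RGS6 region was the most extensive in both sections, with 43.62% of the bins over tissue on plate 5 (exact binomial 95% interval 43.27 to 43.97) and 35.1% on plate 12 (34.77 to 35.44). The NHLH2/AVP region held 23.1% of the bins on plate 5 (22.8 to 23.4) and 16.22% on plate 12 (15.97 to 16.48). The PDE6B/CCN3 region formed a rim with 23.67% and 18.62% of the bins and a mean of only 566 and 643 UMIs per bin. The COL8A1/HES6 region held 4.88% and 3.02% of the bins, and the OSR1/CCN3 region held 2.2% and 1.98%. The remaining 3 regions differed widely in extent between the sections. The APOH/PLLP region held 1.53% of the bins on plate 5 and 11.65% on plate 12, the SST7/PDE6H region 0.91% and 10.77%, and the DNASE2B/SSTR2 region 0.1% and 2.64%. These intervals cover counting error only, and the share of a region also depends on where each section was cut and placed on its chip.

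**Figure D1:**
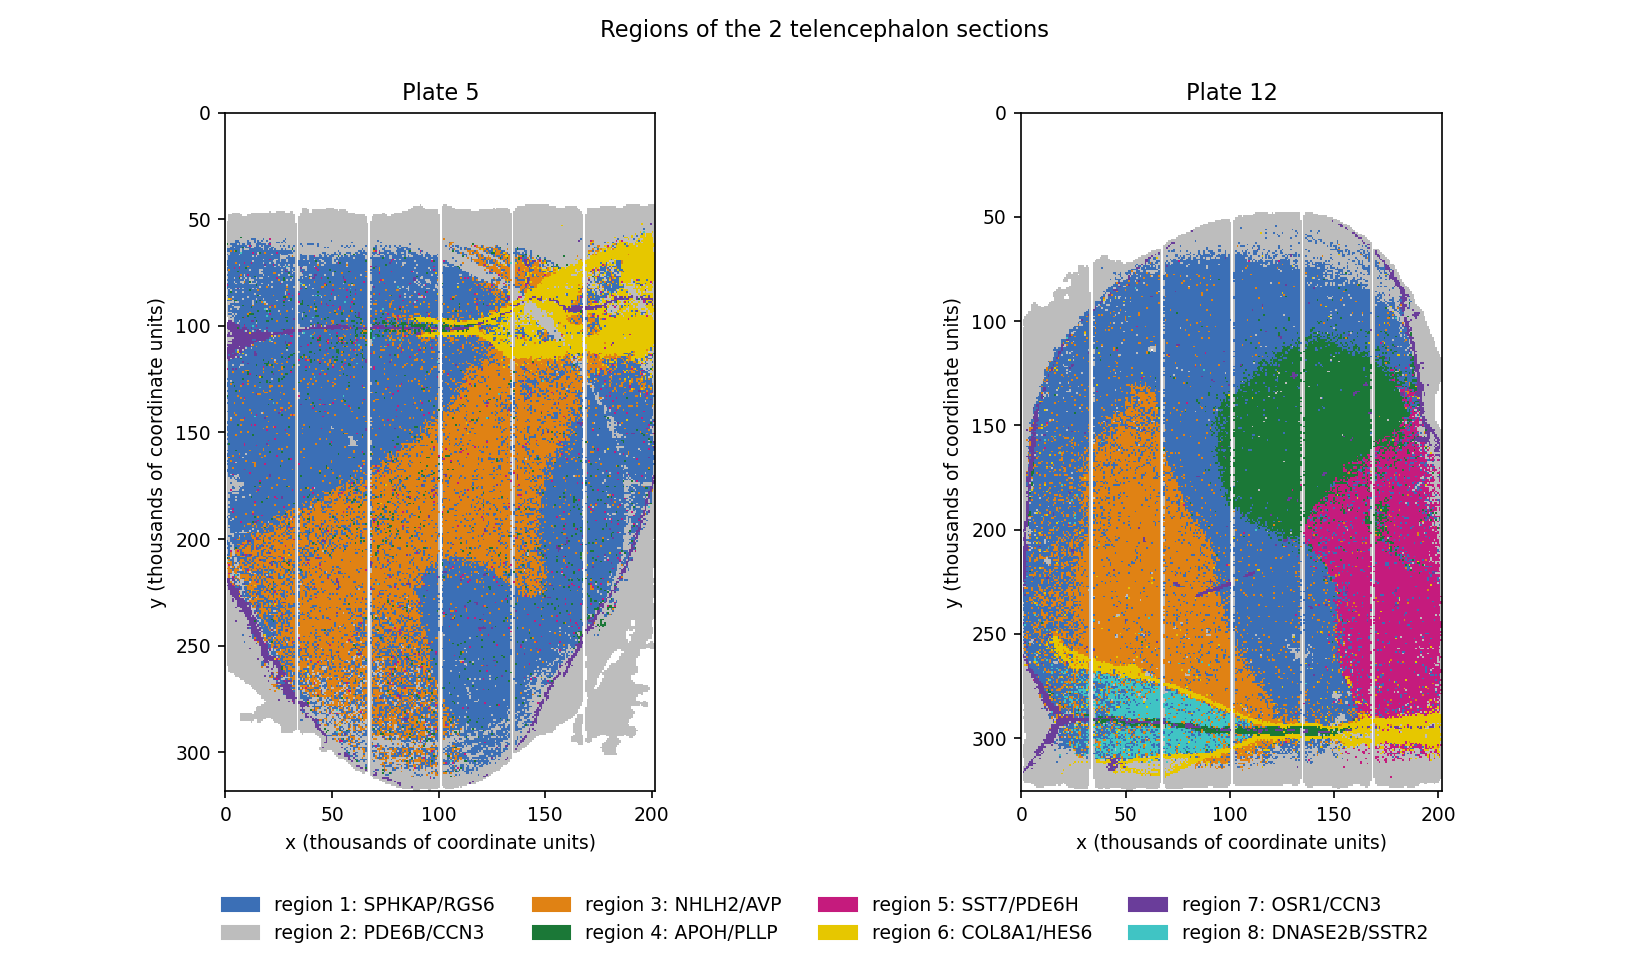
Position of the 8 regions on both sections, drawn from the bins over tissue. Both axes are in coordinate units of the chip divided by 1000, whose physical size is not given in the sources used here, and each colour is a region. The APOH/PLLP region covers 9187 bins on plate 12 against 1184 on plate 5, and the white vertical lines are strips of the chip that hold few UMIs.

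The NHLH2/AVP region was compared with the SPHKAP/RGS6 and PDE6B/CCN3 regions of the same sections. CCK, the neuropeptide cholecystokinin, was at 613 ± 53.8 CPM (SD, n = 2 sections) in the NHLH2/AVP region and at 206 ± 79.0 CPM in the other regions, a log2 difference of 1.58 ± 0.12 (SE). FLT4, the receptor of lymphangiogenic growth factors, was 1.88 ± 0.079 higher on the same scale (51.1 ± 3.62 against 13.4 ± 1.23 CPM). In the opposite direction, the dachshund family transcription factors DACH2 and DACH1 differed by -1.69 ± 0.047 and -1.50 ± 0.090, with 21.3 ± 8.41 against 66.4 ± 24.8 CPM for DACH2 and 16.4 ± 2.25 against 44.6 ± 2.59 CPM for DACH1. NEFM, the medium chain of neurofilament, and FAM163B were also lower in the NHLH2/AVP region, by a log2 difference of -1.23 ± 0.037 (109 ± 16.6 against 247 ± 36.9 CPM) and -1.19 ± 0.082 (79.1 ± 25.6 against 172 ± 23.7 CPM). Adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 3.05e-04 for CCK, 4.04e-05 for FLT4, 8.96e-06 for DACH2, 1.20e-04 for DACH1, 1.08e-05 for NEFM and 2.04e-04 for FAM163B. Of 56 genes followed by name in this comparison, 51 were past the threshold. In 1 fit over all regions that entered, 44 of the 51 lost their call, among them NEFM (adjusted p = 0.157 by edgeR's quasi-likelihood test) and FAM163B (0.148), while CCK, FLT4, DACH2 and DACH1 kept theirs. That fit weighted the SPHKAP/RGS6 and PDE6B/CCN3 regions alike, so its contrast differs from that of their summed UMIs. It also estimated the spread from the sums of all regions that entered. Whether the weights or the spread led to the lost calls was not tested. With DESeq2 12 of the 51 lost their call, none of them these 6. Without the section block all 51 did.

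Of 10 measured genes that pattern the avian pallium, 7 were lower and 2 higher in the NHLH2/AVP region, with the same 7 and 2 when adjusted over the list alone. As a list they did not stand apart from the other genes in limma's camera test (adjusted p = 0.112 with the preset and adjusted p = 0.639 with an estimated correlation). The higher members included FOXP1, a forkhead transcription factor (0.98 ± 0.049, 140.4 ± 36.9 against 69.9 ± 23.6 CPM), and the lower ones included ETV1 (-0.80 ± 0.067), NR2F2 (-0.66 ± 0.12, at -0.32 on plate 5 and -0.91 on plate 12) and LMO4 (-0.51 ± 0.041), all transcriptional regulators. NR2F2 was not lower throughout: on plate 5 it was at 121 CPM in the NHLH2/AVP region against 78.4 and 233 CPM in the 2 largest parts of the SPHKAP/RGS6 region. RORB, not past the threshold, was higher on plate 5 (122.8 against 62.2 CPM) and lower on plate 12 (116.5 against 138.5 CPM). All 4 measured genes of the mammalian pallial amygdala list were lower, and 4 of 4 when adjusted over the list alone. LHX9 was lower by -2.23 ± 0.35 at very low levels of 0.319 against 1.41 CPM. It was at 0.0204 against 0.195 CPM on plate 5 and at 0.617 against 2.63 CPM on plate 12. The other 3 of the 4, NR2F2, ETV1 and MEIS2, also belong to the avian pallial list. Of 8 genes of mammalian upper cortical layers, 3 were higher and 2 lower (3 and 3 when adjusted over the list alone), and of 4 genes of deep cortical layers and 4 of the hippocampus none was past the threshold (for the deep layers 1 was lower, and for the hippocampus none, when adjusted over the list alone). Counts in this and the next paragraph are of genes past an adjusted p of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in the fit of these regions alone. The fit over all regions that entered weighted the SPHKAP/RGS6 and PDE6B/CCN3 regions alike and took its spread from the sums of every such region. In it only 57 of 6518 genes passed, 22 higher and 35 lower. Of the genes named in these paragraphs only CCK, CHRM4, SLC1A2 and ACTA2 kept their call.

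Receptors moved both ways: of 12 channel and receptor genes, 5 were higher and 6 lower, also when adjusted over the list alone. The opioid receptor OPRK1 (1.35 ± 0.085), the muscarinic receptor CHRM4 (0.90 ± 0.046) and the serotonin receptor HTR1B (0.65 ± 0.087, 284 ± 24.7 against 176 ± 19.9 CPM) were higher, and the glutamate receptors GRIA4 (-0.47 ± 0.036) and GRM5 (-0.50 ± 0.043) were lower. Among the interneuron genes 3 of 7 were higher and 1 lower, also when adjusted over the list alone, the higher ones being CCK and the neuropeptides NPY (0.39 ± 0.052, 231 ± 64.7 against 174 ± 64.2 CPM) and VIP (1.33 ± 0.12). Genes of astrocytes were lower in 8 of 9 cases, also over the list alone, among them the glutamate transporter SLC1A2 (-0.56 ± 0.037), the gap junction protein GJA1 (-0.44 ± 0.034) and glutamine synthetase GLUL (-0.33 ± 0.031). Meningeal genes were lower in 6 of 8 cases (7 when adjusted over the list alone), with COL1A1 at -0.47 ± 0.046, and vascular genes in 1 of 6 (6 when adjusted over the list alone), ACTA2 at -0.60 ± 0.081. Of 7 striatal genes other than DRD1, which helped assign the regions, SIX3 and EBF1 were lower (4 genes when adjusted over the list alone). Both were at low levels, SIX3 at 2.17 against 3.50 CPM and EBF1 at 3.39 against 4.83 CPM. DRD1, a dopamine receptor, was at 16.1 ± 0.0754 against 21.5 ± 2.14 CPM as description. All 4 glutamatergic genes other than SLC17A6, which also helped assign the regions, were lower, CAMK2A by -0.56 ± 0.041, with the same count over the list alone. SLC17A6, a vesicular glutamate transporter, was at 947 ± 23.9 against 801 ± 29.8 CPM as description. All 3 GABAergic genes were lower (GAD1 by -0.21 ± 0.043), as were 3 of 4 pallidal and cholinergic genes, with the same counts over the list alone. Among the latter LHX8 was at only 1.18 against 2.43 CPM. Red cell genes were lower in 4 of 6 cases and higher for CA2 (0.68 ± 0.032), also over the list alone. The oligodendrocyte gene UGT8 (-0.87 ± 0.16, at -0.43 on plate 5 and -1.16 on plate 12) and the precursor gene SOX8 (-0.54 ± 0.040) were the only lower members of 6 and 4 (1 and 2 when adjusted over the list alone). Of the ventricular genes EOMES (1.56 ± 0.24, at 0.94 on plate 5 and 1.91 on plate 12) and FOXJ1 (0.36 ± 0.10) were higher and TOP2A lower among 8 (4 higher and 1 lower when adjusted over the list alone). Of 4 immediate early genes ARC was higher (0.24 ± 0.040) and EGR1 lower (-0.48 ± 0.046), also over the list alone, and of 3 choroid plexus and 3 microglial genes none was past the threshold by either adjustment.

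**Figure D2:**
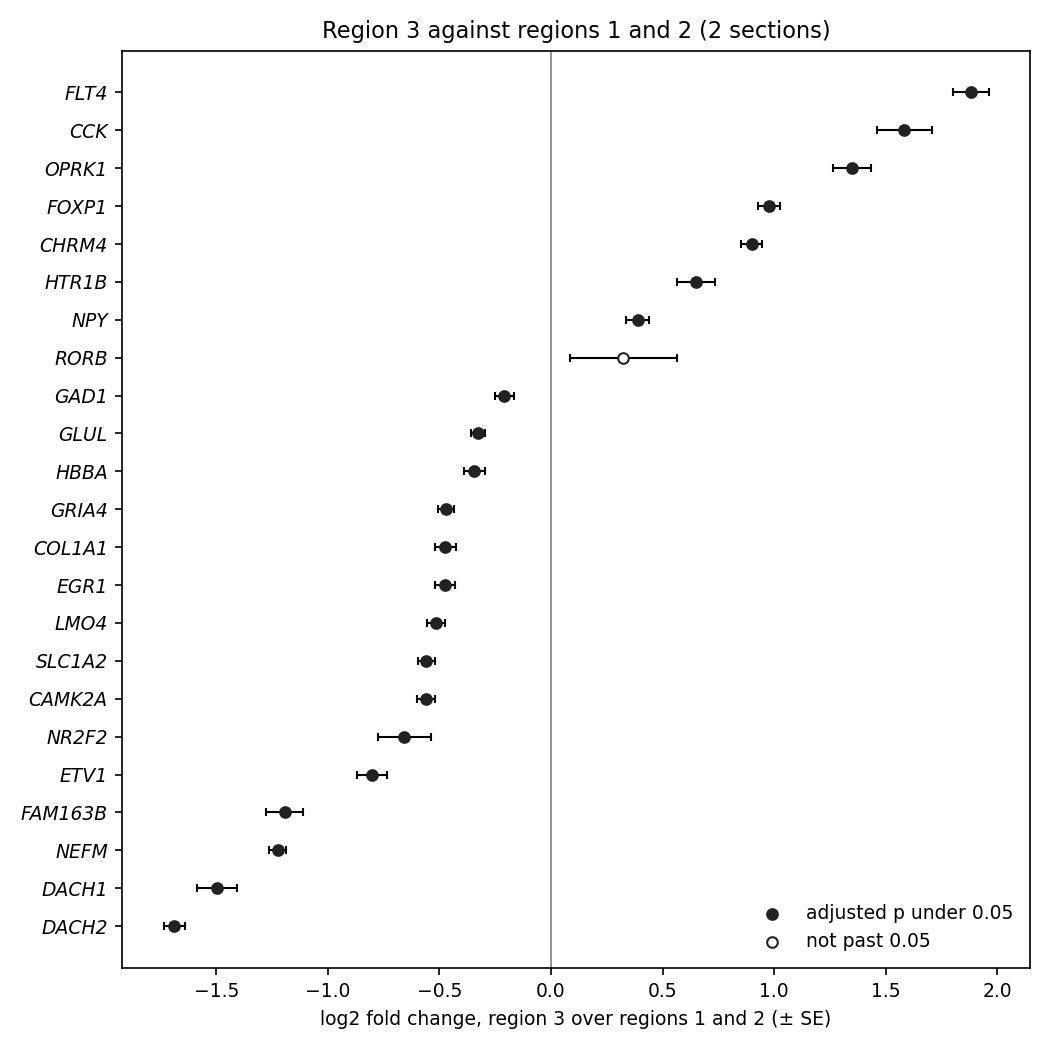
Log2 fold change of genes in the NHLH2/AVP region (region 3) over the SPHKAP/RGS6 and PDE6B/CCN3 regions (regions 1 and 2). Points are the fitted values over 2 sections, and bars are ± 1 SE taken from the test's F statistic. Filled points have an adjusted p under 0.05 by edgeR's quasi-likelihood test and open points do not. FLT4 at 1.88 and DACH2 at -1.69 are at the ends of the range drawn.

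In limma's camera test with a preset correlation and Benjamini-Hochberg adjustment, 5 of the 21 lists stood apart from the other genes in this comparison, all of them lower in the NHLH2/AVP region. For each of the 5 it gave adjusted p = 0.639 with an estimated correlation. With the preset the adjusted p by camera was 0.00285 for the astrocyte and the meningeal list, 0.0181 for the pallial amygdala and the striatal list and 0.0384 for the vascular list. Apart from DRD1, the called members of the striatal list were at the low levels given above. The pallial amygdala list shares 3 of its 4 members with another list and could not be tested without them. Without the anchor genes, an alternative added after the data were seen, the striatal list had an adjusted p of 0.0366 by camera. Among 6834 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 630 were higher and 911 lower in the NHLH2/AVP region, 1541 in all. With no scaling beyond library totals the split was 1157 higher and 890 lower. A fit without the section as a block called 0 genes (1010 at an unadjusted p under 0.05), DESeq2 called 787 of 6569 with the block, and 1 fit over all regions called 57. Only 114 of the called genes differed at least 2-fold, 48 of them higher. The comparison had been laid out as striatal against pallial tissue, but only 1 gene of each class, DRD1 and SLC17A6, was measured among the anchor genes that assigned it, so these class names are not used and both genes are description only.

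**Figure D3:**
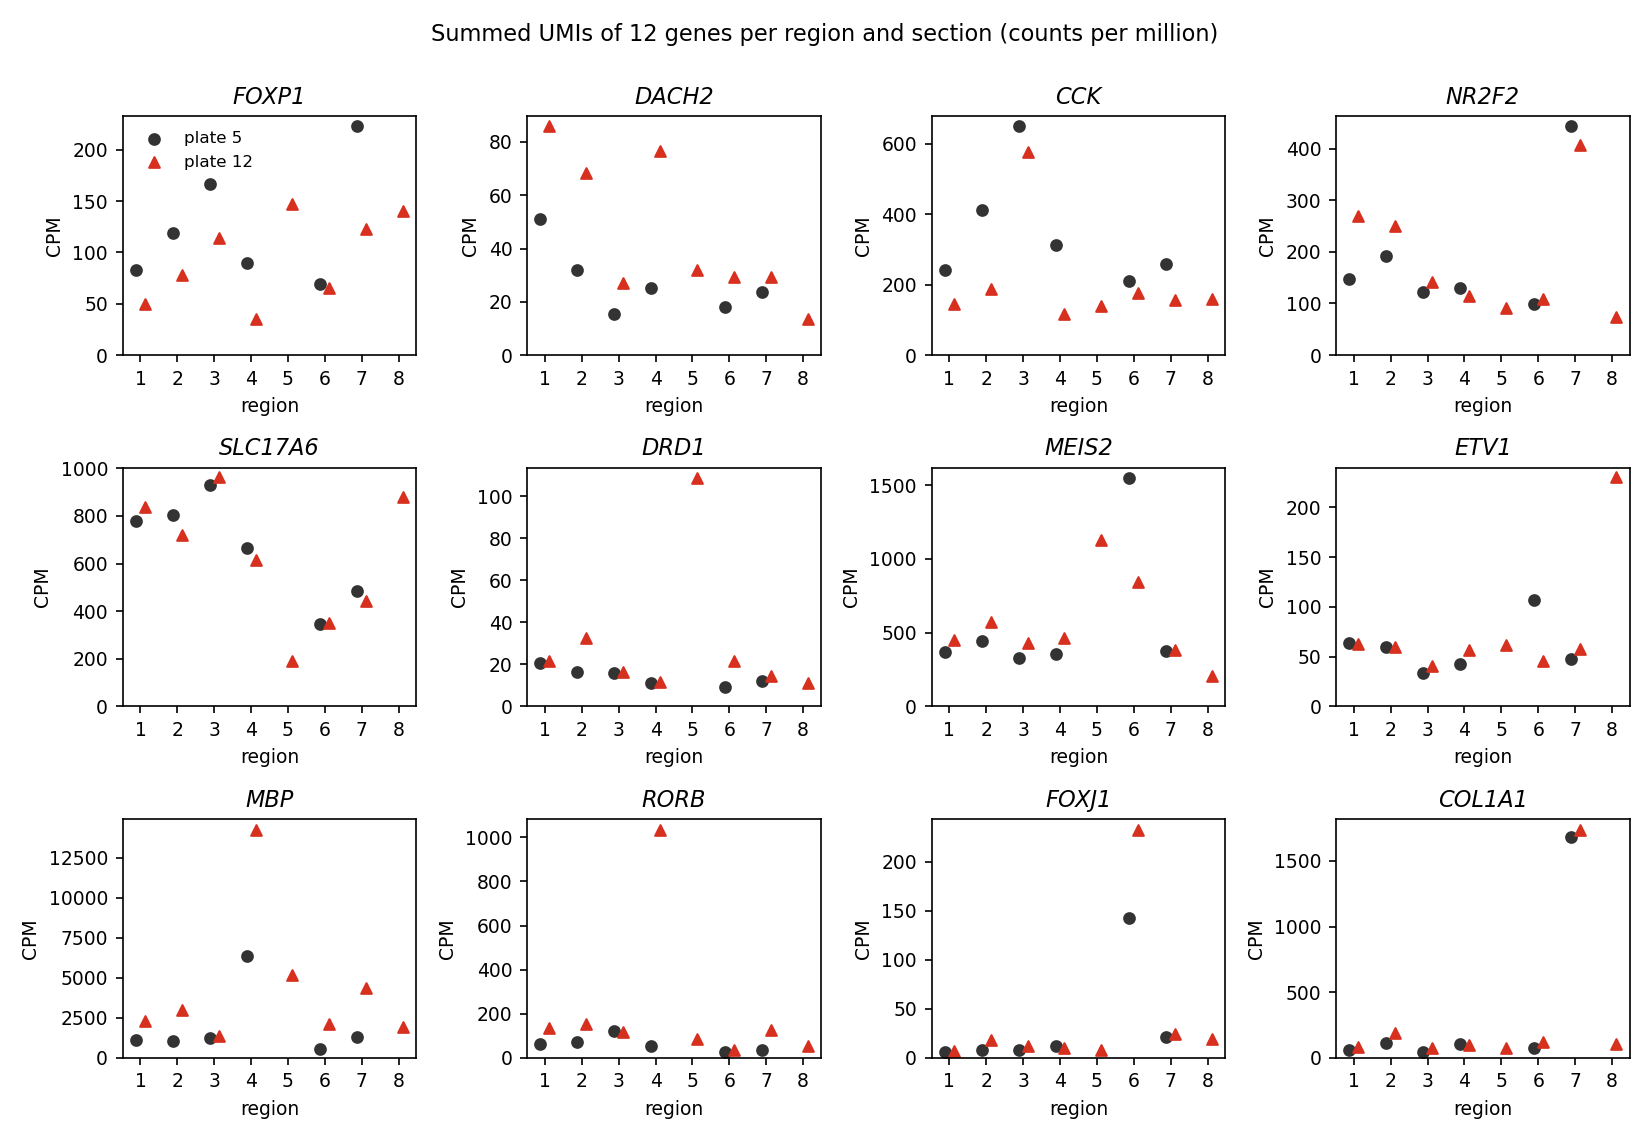
CPM of 12 genes in each region (1 to 8, numbered by size, as in the map of the regions), with 1 point per section. Circles are plate 5 and triangles plate 12, each axis starts at 0, and a region under 1% of the bins of a section has no point for it. RORB stands at 1032.5 CPM in region 4 of plate 12 against 53.2 CPM on plate 5.

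The APOH/PLLP region carried the genes of myelin. All 6 measured oligodendrocyte genes were higher there than in all other bins over tissue, also when adjusted over the list alone. CNP, an enzyme of the myelin sheath, was higher by a log2 difference of 2.84 ± 0.25 (681 ± 8.90 against 104 ± 49.1 CPM, SD, n = 2 sections), UGT8, which makes the lipid galactocerebroside, by 2.89 ± 0.32 (3.54 on plate 5 and 2.04 on plate 12), and the transcription factors SOX10 and OLIG2 by 2.10 ± 0.20 and 0.99 ± 0.17. The myelin basic protein gene MBP (2.55 ± 0.27) had served as an anchor of the region's class and is given as description. SOX8 was the only higher gene of 4 oligodendrocyte precursor genes (1.09 ± 0.18; 1 gene over the list alone too), and the choroid plexus gene TTR was lower (-2.52 ± 0.31, 2.46 ± 0.257 against 13.9 ± 1.21 CPM). RORB and the calcium-binding protein PVALB differed between the sections: RORB was at 1032.5 against 119.9 CPM in the other bins of plate 12 but at 53.2 against 79.1 CPM on plate 5, and PVALB at 3536 against 635 CPM on plate 12 and 256 against 259 CPM on plate 5. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 5.85e-04 for CNP, 0.00176 for UGT8, 0.0318 for OLIG2, 0.519 for RORB and 0.355 for PVALB.

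Of 6936 genes, 76 were higher and 5 lower in the APOH/PLLP region by edgeR's quasi-likelihood test. Without the section block 0 were called (532 at an unadjusted p under 0.05). Clustering on the other part of the genes called 433, no filter on low counts 162, resolution 1.0 53 and bins of 400 units 46. The fit over all regions that entered called 1126, but against the unweighted mean of the other regions and not all other bins. Its spread too was taken from the sums of all these regions. The oligodendrocyte list stood apart in limma's camera test (median log2 difference 2.70, adjusted p = 3.38e-08 with the preset and adjusted p = 0.610 with an estimated correlation). Lists that were lower by the same test were the channel and receptor and the striatal list (both adjusted p = 0.00818), with 0 members past the threshold in either (3 in each when adjusted over the list alone), and the choroid plexus and ventricular lists (both adjusted p = 0.0211), with 1 of 3 and 0 of 8 members lower (1 and 3 when adjusted over the list alone). For each of these 4 lower lists camera gave adjusted p = 0.610 with an estimated correlation. The other bins included the COL8A1/HES6 region, with TTR at 187 and HES5 at 246 CPM. For these 2 genes the SPHKAP/RGS6 region had 4.34 and 10.5 CPM against 2.46 and 10.2 CPM in the APOH/PLLP region. On plate 12 the other bins also included the SST7/PDE6H region, where the striatal list had a median log2 ratio of 2.01. The lower medians came mostly from plate 12, at -0.95 for the striatal, -0.86 for the channel and receptor and -0.85 for the ventricular list, against -0.13, -0.16 and -0.24 on plate 5. This region took 1184 bins on plate 5 and 9187 on plate 12, and genes at least 2-fold apart numbered 52 on plate 5 and 252 on plate 12, 45 of them in both.

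Genes of the ventricular lining and of young neurons marked the COL8A1/HES6 region. All 8 measured members of that list were higher than in the other bins over tissue, also when adjusted over the list alone. FOXJ1, the regulator of motile cilia, was higher by 4.36 ± 0.14 (188 ± 63.0 against 8.56 ± 1.92 CPM, SD, n = 2 sections), the Notch target HES5 by 4.08 ± 0.14, EOMES, a transcription factor of intermediate progenitors, by 2.51 ± 0.19, the topoisomerase of dividing cells TOP2A by 1.93 ± 0.13 and DCX, a microtubule protein of migrating neurons, by 1.92 ± 0.16. The intermediate filament gene VIM was at 1491 against 187 CPM on plate 5 and 2269 against 257 CPM on plate 12. OTX2 was higher by 5.47 ± 0.56 (7.18 ± 3.41 against 0.154 ± 0.0837 CPM), and TTR, an anchor given as description, stood at 187 ± 36.3 against 5.48 ± 2.04 CPM. The remaining choroid plexus gene, AQP1, was not past the threshold (-0.19 ± 0.12, at 0.23 on plate 5 and -0.47 on plate 12). DLX5 (2.11 ± 0.14), MEIS2 (1.32 ± 0.12, at 2.10 on plate 5 and 0.68 on plate 12) and the microglial receptor CSF1R (0.60 ± 0.13) were also higher, as were all 3 microglial genes, also when adjusted over the list alone. Of the GABAergic genes beside DLX5, DLX6 was higher (0.94 ± 0.23) and GAD1 lower (-0.40 ± 0.12, at 0.085 on plate 5 and -0.74 on plate 12). The SEs here rest on a spread pooled over genes and do not widen where the sections disagree, as for MEIS2 and GAD1. Of 5 glutamatergic genes 4 were lower, also when adjusted over the list alone, with SLC17A6 at 349 ± 3.47 against 784 ± 52.6 CPM and CAMK2A at -1.41 ± 0.12, and NEUROD1 was higher (0.97 ± 0.13). The immediate early gene ARC was lower (-1.43 ± 0.13).

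By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1500 of 6949 genes were higher and 1478 lower in the COL8A1/HES6 region. Without the section block 1197 were called. With no scaling beyond library totals 1601 were higher and 1103 lower. The ventricular list stood apart in limma's camera test (median 2.22, adjusted p = 4.13e-05 with the preset and adjusted p = 0.864 with an estimated correlation). With the preset 5 lists were lower, and for each of them too it was adjusted p = 0.864 with an estimated correlation. Oligodendrocyte genes were lower in 6 of 6 cases, vascular genes in 5 of 6 and channel and receptor genes in 9 of 12, red cell genes in 4 of 6 (each adjusted p = 0.0104 by camera), and immediate early genes in 4 of 4 (adjusted p = 0.0125); adjusted over the list alone these counts were 6, 5, 10, 5 and 4. Without its anchor genes the oligodendrocyte list no longer stood apart (adjusted p = 0.104 by camera with the preset).

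The OSR1/CCN3 region, a thin line along the tissue edge and across the sections, carried the genes of connective tissue. Of 8 meningeal genes 7 were higher than in the other bins over tissue, also when adjusted over the list alone, and ALDH1A2 (-0.19 ± 0.11) was not past the threshold. The proteoglycan genes OGN, LUM and DCN were higher by 5.40 ± 0.21, 4.67 ± 0.20 and 3.76 ± 0.076, the collagen gene COL3A1 by 4.38 ± 0.10, and the anchor gene COL1A1, given as description, stood at 1708 ± 35.9 against 73.8 ± 20.6 CPM (SD, n = 2 sections). Vascular genes were higher in 5 of 6 cases (6 when adjusted over the list alone), with MYH11, a smooth muscle myosin, at 4.86 ± 0.26 and CDH5, the endothelial cadherin, at 0.89 ± 0.15. Haemoglobin and other red cell genes were higher in 5 of 6 cases, HBBA by 1.18 ± 0.067, while CA2 was lower by -0.23 ± 0.071, with the same counts over the list alone. All 5 glutamatergic genes were lower, SLC17A6 by -0.79 ± 0.066, as were 10 of 12 channel and receptor genes, with the same counts over the list alone.

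By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1164 of 6919 genes were higher and 1180 lower in the OSR1/CCN3 region. Without the section block 1025 were called. With no scaling beyond library totals 1295 were higher and 978 lower. In limma's camera test the adjusted p was 6.07e-05 for the meningeal list, 6.42e-04 for the vascular, 0.00102 for the channel and receptor, 0.00789 for the glutamatergic and 0.0124 for the red cell list, and for all 5 it was adjusted p = 0.822 with an estimated correlation. In 1 simulation of the NHLH2/AVP comparison, a single planted list of 9 genes changed 2-fold had adjusted p = 0.906 in limma's camera test with an estimated correlation and 2.34e-23 with the preset one, so the estimated correlation missed that list. The simulated genes were drawn independently of each other, so this cannot show whether the preset holds for real lists, whose members may vary together.

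The SST7/PDE6H and DNASE2B/SSTR2 regions each held under 1% of the bins of plate 5, so they were described on plate 12 alone, with no replicate and no test. In the SST7/PDE6H region DRD1 was at 109 CPM against 19.0 CPM in the other bins of plate 12, a ratio of 5.71 (95% Poisson interval 5.39 to 6.05). The LIM homeobox gene ISL1 had a ratio of 13.8 (12.2 to 15.7), the vesicular acetylcholine transporter SLC18A3 11.5 (10.5 to 12.7), the amyloid peptide hormone IAPP 13.6 (13.0 to 14.4) and DLX6 5.16 (4.69 to 5.67). Of 8 striatal genes 7 were higher, with a median log2 ratio of 2.01, at percentile 100 among 10000 random lists matched on expression. Of 3 GABAergic genes 3 were higher, at percentile 99.99, and of 5 glutamatergic genes 4 were lower, with a median of -1.91 at percentile 0 and SLC17A6 at 191 against 803 CPM. DRD1 belonged to the anchor genes, but no gene of these lists had entered the clustering. The random lists held independently drawn genes, while members of a real list may vary together. Many of the other lists also lay near percentile 0 or 100 here, so an extreme percentile is description and not a test.

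In the DNASE2B/SSTR2 region of plate 12, the transcription factor ETV1 was at 230.1 against 56.4 CPM (ratio 4.08, 3.84 to 4.34) and the glutamate receptor GRIA1 at 58.0 against 14.6 CPM (3.97, 3.51 to 4.48). The phosphodiesterase PDE5A had a ratio of 6.39 (5.51 to 7.38) and the oestrogen-binding receptor GPER1 of 4.79 (4.39 to 5.22). All 4 hippocampal genes were higher, with a median log2 ratio of 0.93 at percentile 99.97 among the random lists, among them the mineralocorticoid receptor NR3C2 (3.43, 3.23 to 3.64) and LEF1, an effector of Wnt signalling (3.22, 2.93 to 3.52), with DKK3 at 1.15 (1.08 to 1.23). PROX1, the remaining one, was near the limit of detection at 1.76 against 1.45 CPM. Lists at the other extreme, each at percentile 0, were the avian pallial list to which ETV1 belongs (7 of 10 genes lower, median -0.99), the oligodendrocyte list (6 of 6 lower), the pallidal and cholinergic list (6 of 7 lower) and the striatal list (8 of 8 lower). The other bins of plate 12 included the APOH/PLLP region, with MBP at 14248 CPM, and the SST7/PDE6H region, with DRD1 at 109 CPM. These intervals cover counting error only, and the percentiles make no allowance for list genes that vary together.

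Summed over all genes the sections were close, with Pearson's r of 0.993 and Spearman's rho of 0.993 between their log2 CPM across 15438 genes, which are not independent replicates, and 184 genes at least 2-fold apart. Of 81 list genes with a mean of at least 20 CPM over the sections, 8 were at least 2-fold higher on plate 12 and 0 lower. Among these were PVALB (ratio 4.01, 95% interval 3.97 to 4.05), MBP (3.44), RORB (3.15), CNP (2.72), ACTA2 (2.38), CALB2 (2.30) and LMO4 (2.11). With 1 section each, the ratios have no replicate check.

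**Figure D4:**
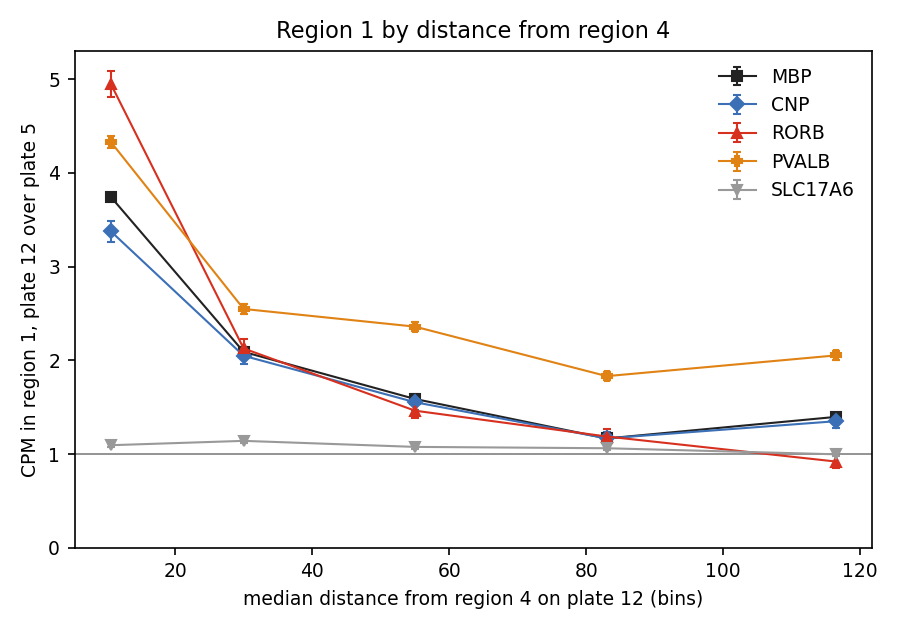
Ratio of plate 12 to plate 5 in CPM within the SPHKAP/RGS6 region (region 1), for 5 groups of plate 12 bins by their distance from the APOH/PLLP region (region 4). The x axis is the median distance of each group in bins, and bars are 95% Poisson intervals of the plate 12 counts. The myelin gene MBP falls from a ratio of 3.74 nearest to region 4 to 1.17 in the group at 83.0 bins and stands at 1.40 in the farthest. CNP falls from 3.38 to 1.17 and 1.35 in the same groups, and PVALB from 4.33 to 1.83 and 2.05. RORB falls from 4.95 nearest to region 4 to 0.921 in the farthest group. SLC17A6 lies between 0.998 and 1.14.

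Moran's I, a measure of how alike neighbouring bins are, was computed for 5153 genes after thinning each bin to 500 UMIs. It was above 0.05 in both sections for 36 genes (41 on plate 5 and 84 on plate 12 taken singly), while genes with shuffled bins reached at most 0.0109. The highest values by the lower of the sections belonged to ENSGALG00000065929 (0.699 on plate 5 and 0.708 on plate 12) and ENSGALG00000064050 (0.661 and 0.718), which have no symbol, and to another gene without one. MBP followed with 0.347 and 0.704, and among the next were PTGDS, the prostaglandin D synthase of the meninges (0.347 and 0.279), COL1A1 (0.282 and 0.248), COL1A2 (0.217 and 0.226), VIM (0.208 and 0.214) and a further gene without a symbol. Across genes the values of the sections correlated with Pearson's r of 0.843 and Spearman's rho of 0.420.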

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

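The test of off-tissue RNA was chosen before its result was seen. UMIs outside the tissue mask, a signal in data that no comparison uses, made up 0.157% of the UMIs on plate 5 and 0.494% on plate 12. The share depended on the bin side that set the mask, at 0.375% and 0.550% with 400 units, 0.984% and 1.01% with 100 units and 3.11% and 2.39% with 50 units, where the order of the plates turned, and 7.94% and 7.22% with 25 units. A candidate explanation is RNA that left the tissue of the same section. Of 68 genes at least 2-fold apart between the sections' tissue, 98.5% differed in the same direction off tissue, which is consistent with that explanation. Off-tissue levels also correlated across genes more with the section's own tissue (r = 0.900 on plate 5 and 0.971 on plate 12) than with the other section's (0.870 and 0.959). A mask that leaves thin tissue outside stays open, and so does one that counts RNA beside the tissue as tissue. The mask began at 58.2 smoothed UMIs per bin on plate 5 and 100 on plate 12, and the PDE6B/CCN3 rim held a mean of 566 and 643. Whether that rim holds such RNA was not tested, and no biological explanation was tested.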

How the results depend on the processing

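The alternatives without the PDE6B/CCN3 region or the anchor genes and all those for the other regions, except no scaling, were chosen after the result was seen. In the comparison of the NHLH2/AVP region edgeR's quasi-likelihood test called 1541 genes, and 1249 to 2047 under another scaling, no filter, double bins, the other part of the genes, resolution 1.0, joint standardisation, the stricter mask, no ribosomal and haemoglobin genes, or no PDE6B/CCN3 region. The count was 0 without the section block and 787 with DESeq2. It was 57 in 1 fit over all regions that entered, a contrast of unweighted means with its spread taken from all these regions. In that fit 44 of the 51 called genes followed by name lost their call (12 with DESeq2). At resolution 0.25 and with bins of 400 units no separate region matched the NHLH2/AVP region, which gave no value. The APOH/PLLP region (81 genes) had 0 without the block, 162 without the filter, 433 with the other part of the genes, 53 at resolution 1.0, 46 with bins of 400 units (where 43.1% of the matched bins lay in it), 1126 in 1 fit over all regions, and 54 to 117 otherwise. Genes at least 2-fold apart there numbered 52 to 252 with either section alone, against 88. It gave no value with double bins, resolution 0.25, joint standardisation or the stricter mask, where it did not enter. Without the block the COL8A1/HES6 region had 1197 genes (2978 in the fit reported) and the OSR1/CCN3 region 1025 (2344), and they had 2082 to 2929 and 1582 to 2338 otherwise; the stricter mask and bins of 400 units left no OSR1/CCN3 region. With an estimated correlation 0 lists passed in limma's camera test in each of the 4 comparisons, against 5, 5, 6 and 5 with the preset. Across 8773 genes with at least 10 CPM in either section, r between sections was 0.980. Moran's I was above 0.05 in both sections for 41 genes without thinning and 35 with double bins, against 36, and for 41 and 84 on plates 5 and 12 singly. With no scaling beyond library totals the split went from 630 higher and 911 lower to 1157 and 890 for the NHLH2/AVP region, from 1500 and 1478 to 1601 and 1103 for the COL8A1/HES6 region, and from 1164 and 1180 to 1295 and 978 for the OSR1/CCN3 region. Without members shared with another list 4 lists passed for the NHLH2/AVP region, since the pallial amygdala list had too few left to test. Without the anchor genes 5, 4, 5 and 5 lists passed, since the choroid plexus list of the APOH/PLLP region had too few members left and the oligodendrocyte list of the COL8A1/HES6 region lost its call. Apart from GAD1 in the COL8A1/HES6 region, no gene past the threshold that the text names turned its direction with either section alone. RORB in the NHLH2/AVP comparison, RORB and PVALB in the APOH/PLLP region and AQP1 in the COL8A1/HES6 region were not past it and differed in direction between the sections. The cause of these changes was not tested. Bins under 500 UMIs were too shallow for Moran's I, and the share of changed genes recovered in simulated counts sets what the tests can miss.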

Other observations

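The test of the shallow bins was chosen after the result was seen, and that of the swaths before, except that the lookup of genes across sections came after it.

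The SST7/PDE6H region of plate 12 differed from the other bins of that section in more than striatal genes. The LIM-only gene LMO4 was at 547 against 124 CPM (ratio 4.41, 95% Poisson interval 4.30 to 4.52), the serotonin receptor HTR1B at 688 against 189 CPM (3.63, 3.56 to 3.71), NPY at 621 against 232 CPM (2.67, 2.62 to 2.73), and MEIS2 at 1129 against 460.0 CPM (2.45, 2.42 to 2.49). Oligodendrocyte genes were higher in 6 of 6 cases (percentile 99.59 among random lists), meningeal genes lower in 7 of 8 (percentile 0) and choroid plexus genes lower in 3 of 3 (percentile 0.03). The other bins of plate 12 included the OSR1/CCN3 region, with COL1A1 at 1734 CPM, and the COL8A1/HES6 region, with TTR at 212 CPM. Of 7 pallidal and cholinergic genes 6 were higher, with LHX8 at a ratio of 7.78 (6.92 to 8.76). CAMK2A, a member of the glutamatergic list, was higher too (1.40, 1.38 to 1.42).

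The APOH/PLLP region differed between the sections in more than its extent. On plate 12 its highest genes with a symbol by log2 ratio included RORB, FMOD, MBP, APOD, PVALB, SCRT2 and CNP, and GAD1 was at 583 against 270.2 CPM (ratio 2.16, 2.11 to 2.20). On plate 5 they included UGT8, CNP, TMEM88B, CRYAB, MBP, SCRG1 and NKX6-2, and GAD1 was at 197 against 194 CPM (1.02, 0.931 to 1.11). Whether the bins of this region are the same kind of tissue in both sections was not tested.

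Genes that differed between the NHLH2/AVP region and the SPHKAP/RGS6 and PDE6B/CCN3 regions could reflect the shallow bins of the rim or the imaging swath of the chip. Leaving the PDE6B/CCN3 region out gave 1572 genes by edgeR's quasi-likelihood test, which argues against the shallow bins as the whole cause. The 114 genes chosen for a pooled difference of at least 2-fold were followed within 11 imaging swaths that held both kinds of region. They kept the pooled direction in a median share of 0.909 of swaths (lowest 0.364, 25 genes in every swath, and 75 and 66 genes in the weakest swath of plates 5 and 12). But these swaths are parts of the bins that chose the genes. The median log2 size was 0.74 within swaths, with 1 CPM added to both levels, against 1.33 in the pooled fit without it. These sizes are unlike measures, since adding 1 CPM shrinks low levels and only 23 of the 114 genes had 20 CPM. Of 27 genes at 20 CPM or more and at least 2-fold apart on plate 12, 21 kept that direction in all 6 swaths of plate 5 (lowest share 0, median log2 size 0.93 against 1.05 over all its bins), and of 31 chosen on plate 5, 16 did in all 5 swaths of plate 12 (lowest share 0.2, median 1.06 against 1.17), which argues against the swath as the whole cause. A regional difference in these brains stays open as a hypothesis, and so does a loss of size in bins that mix both kinds of tissue, and neither this nor position along a swath was tested.

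On plate 5 the SPHKAP/RGS6 region lay on both sides of the NHLH2/AVP region, in connected parts of 14715 and 10833 bins. Over 3271 testing genes with at least 20 CPM, 13 were at least 2-fold apart between the parts, against 42 and 59 between each part and the NHLH2/AVP region. The median absolute log2 differences were closer, at 0.098 between the parts against 0.121 and 0.174. Clustering by expression had put both parts in 1 region, which by itself favours a smaller difference between them. The largest differences between the parts among genes with a symbol were TFAP2D (14.7 and 45.6 CPM), NR2F2 (78.4 and 233 CPM, with 121 CPM in the NHLH2/AVP region), OPRL1 (69.7 and 28.4 CPM) and STUM (263 and 114 CPM), genes singled out after their values were seen.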
